A study of Homo sapiens with 16 samples.

How the data were processed

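RNA sequencing was done on 16 libraries of tumour tissue from 8 participants with endometrial cancer. Each participant gave a diagnostic biopsy and a surgical resection specimen, taken 3 to 4 weeks apart, per the labels and the series' design text. Of the participants, 5 had been randomised to a very-low-carbohydrate, ketogenic diet between both samples, and 3 continued their usual diet. Participants are called K1 to K5 (ketogenic diet) and S1 to S3 (standard diet) here; the numbers only name them.

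The authors deposited 1 table of raw read counts, with 25356 gene symbols in its lines and the 16 libraries in its columns. All 16 columns were matched to a sample by name, and no column of another sample was present. FastQC, STAR-Fusion, HTSeq and DESeq2 1.42.1 are named, with the builds GRCh37 and hg19, per the submitters' processing notes, which give no role for any of them. The aligner's settings, the annotation release and whether strand was used in counting are not given in the sources used here. Because strand was not stated, reads of overlapping and antisense genes cannot be told apart, and microRNA features lie within longer transcripts. Libraries were made with a kit that selects polyadenylated RNA or a kit that depletes ribosomal RNA, per the labels' protocols, which do not say which library had which kit. Total counts ran from 12544756 to 56187724 per library. No pair of libraries within a group agreed within sampling noise: the lowest chi-square over its degrees of freedom was 268 among 26 pairs.

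The counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, robust dispersion, quasi-likelihood F-test, Benjamini-Hochberg adjustment, threshold 0.05). Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 19302 genes in the comparisons within participants, 17956 in the biopsies and 18291 in the resections. One model over the 16 libraries held a term for each participant and the change from biopsy to resection in each diet. It gave 4 comparisons, namely the change on the ketogenic diet, the change on the standard diet, the difference of the changes and the mean of both changes. The diets were also compared within the biopsies and within the resections, with 5 libraries against 3. Fold changes are log2 values, with a standard error taken as the fold change divided by the square root of F. The common biological coefficient of variation was 0.435 within participants, 0.723 in the biopsies and 0.730 in the resections.

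The participant block was part of the first-choice model, since both samples of a pair come from 1 person; the fit without it was an alternative. The pairing comes from the labels. Deviations from the group means correlated at 0.28 to 0.80 between both samples of a participant, against a median of -0.10 and a highest value of 0.39 between participants, and in 8 of 8 participants the best match was the own sample.

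The 39 gene lists cover metabolism, hormone and stress response, immune cells, stroma, epithelium and technical sources of RNA. They were fixed with the models, the alternatives and the rule for named genes before the data were examined. The list of mitochondrially encoded genes had 0 members in the table and was not analysed here, which left 38. Lists with at least 3 members were tested with fry (limma 3.58.1), which asks whether a list's genes move on balance one way. camera was run as an alternative with a preset correlation of 0.01 and with an estimated correlation. Members were also tested with p-values adjusted over the list alone. A list score is the mean log2(CPM + 0.5) of the members; its change between the samples of a participant was compared between diets with an exact two-sided permutation test over the 56 assignments of 5 of 8 participants, whose smallest possible p is 0.0179. Changes within a diet were tested by exact sign flips, whose smallest possible p is 0.0625 with 5 pairs, 0.25 with 3 and 0.00781 with 8.

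The rule for named genes took, in each comparison, the genes past the threshold; where fewer than 5 passed, it took the 5 with the smallest p in each direction, named as not passing. It also took up to 2 members per list and direction, and a fixed set of genes of insulin signalling, metabolism, proliferation, hormone response and immune cells. XIST, Y-linked genes, antigen receptor segments and clone names were left out. EPYC, FABP7, SNTN, MIR29B2, MIR106B, ZFR2 and SLCO6A1 are given no fold change, since most libraries of a group held few or no reads of each. Some named genes are not reported here. Genes called by DESeq2 alone, and the microRNA features as a class, were chosen after their values were seen.

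The alternatives were median-of-ratios scaling, no low-count filter, a filter of CPM of at least 5 in 3 samples, DESeq2 1.42.0, limma voom with quality weights, the fit without the block, the libraries of that diet alone, a score of non-polyadenylated RNAs as a covariate, removal of ribosomal protein, non-polyadenylated and haemoglobin genes, and each participant left out in turn. For list scores they were a pseudocount of 2 and the median of the members. Leaving out S3 and K5 together, the list tests with each participant left out and the sign flips over 8 participants were chosen after seeing the data.

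The edgeR step was tested on simulated counts with the real means and library sizes and 50 genes changed at each size. The changed genes were drawn above a floor of mean expression, and simulated genes vary independently. A further 20 lists of 30 genes were shifted 2-fold in the same counts. The recovery rates therefore hold for data with many changed genes and may be too high for the real counts. In the change on the ketogenic diet it recovered 22% of genes changed 2-fold, 78% at 4-fold, 96% at 8-fold and 100% at 16-fold, with 6 false calls among 18502 unchanged genes. In the change on the standard diet it recovered 10%, 52%, 84% and 96%, and in the difference of the changes 0%, 32%, 56% and 82%. In the mean change it recovered 48%, 90%, 94% and 100%. In the biopsies it recovered 0%, 6%, 54% and 70%, and in the resections 0%, 4%, 36% and 68%. fry recovered 20 of 20 lists shifted 2-fold in each comparison, on simulated genes that vary independently; of 20 lists left unshifted it called 2 in the biopsies and 0 in each of the other comparisons.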

Results

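RNA was sequenced from tumour tissue of 8 participants with endometrial cancer, which arises in the lining of the uterus. Each gave a diagnostic biopsy and, 3 to 4 weeks later, a surgical resection specimen. In 5 pairs of samples (K1 to K5) the participant ate a ketogenic diet in between, which restricts carbohydrate so that ketone bodies and fat supply more of the energy. In the other 3 pairs (S1 to S3) the usual diet was kept. The design asks how tumour expression changes under each diet, and in particular how insulin signalling genes and immune cell genes behave. In the order K1 to K5, the biopsies held 24986763, 42341128, 44501753, 28861317 and 42359269 counts, and the resections 31435070, 44958215, 37375616, 46826489 and 23498830. In the order S1 to S3, the biopsies held 27370508, 38783294 and 24564047 counts, and the resections 56187724, 39089075 and 12544756. Between 19733 and 21578 genes had at least 1 count in a library. Gene values below are log2 fold changes ± standard error from edgeR, with a participant term where pairs are compared, and levels are CPM as mean ± SD.

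Both libraries of S3 carried far more RNA without a poly(A) tail than the other 14. The score of the non-polyadenylated RNA list was 3.19 and 3.28 in S3 and -0.421 to 0.486 elsewhere. RMRP, the RNA part of a mitochondrial RNA processing enzyme, stood at 310 and 956 CPM in S3 and at 0.135 to 7.06 CPM elsewhere. RPPH1, the RNA part of RNase P, stood at 249 and 2790 CPM in S3 and at 0.0268 to 7.55 CPM elsewhere. MALAT1, a nuclear long non-coding RNA, reached 23800 and 36900 CPM in S3 and also 23800 CPM in the resection of K5, against 395 to 1650 CPM in the remaining 13 libraries. S3, if taken as a batch, holds the standard diet only, so no value of a diet comparison can be had within it. Results without both S3 and K5 (4 pairs against 2), a setting chosen after seeing the data, stand beside the results. That the remaining libraries share a preparation is assumed, since no label gives it.

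On the ketogenic diet, several of the genes with a small p and higher values in the resections were immediate early genes, which cells transcribe within minutes of a stimulus. CYR61, a secreted matrix protein gene, stood at 93.5 ± 88.6 CPM in the biopsies and 585 ± 420 CPM in the resections (2.55 ± 0.49, higher in 5 of 5 pairs). The transcription factor genes EGR3 (2.27 ± 0.50), NR4A1 (3.16 ± 0.76) and EGR1 (2.22 ± 0.55) the actin-binding protein gene CCDC88A (0.97 ± 0.20) and the histone gene HIST2H2BF (2.00 ± 0.46) lay the same way. Lower in 5 of 5 resections were MIR200A (-3.61 ± 0.50) and MIR200B (-3.57 ± 0.61), which carry microRNAs of epithelial cells, ARHGAP40 (-2.79 ± 0.54), and VTCN1 (-1.57 ± 0.34), an inhibitory ligand of T cells that stood at 250 ± 112 and 113 ± 80.1 CPM. The microRNA features hold few reads (MIR200A at 2.49 ± 1.49 CPM in the biopsies) and overlap longer transcripts, so their values are uncertain.

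With edgeR, 0 of 19302 genes passed the threshold in this comparison; the smallest adjusted p was 0.674, and 655 genes (304 higher, 351 lower) had an unadjusted p under 0.05. DESeq2 called 33 genes (12 higher, 21 lower), and limma voom called 0. The DESeq2 calls include CYR61 (adjusted p = 7.94e-05), EGR3 (0.00179), NR4A1 (0.00042), EGR1 (0.00743), CCDC88A (0.01), MIR200A (3.69e-08), MIR200B (8.25e-05), ARHGAP40 (7.94e-05) and VTCN1 (0.00806). Without S3 and K5, edgeR again called 0 genes, with 736 at an unadjusted p under 0.05. The fold changes there were 2.06 ± 0.37 for CYR61, 2.41 ± 0.63 for EGR3, 1.84 ± 0.57 for EGR1, -3.27 ± 0.48 for MIR200A and -1.79 ± 0.38 for VTCN1.

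Of the 37 measured members of the immediate early and handling stress list, 36 were higher and 1 lower in the resections of the ketogenic group, with a median of 1.00. Adjusted over the list alone, BTG2, CTGF, CYR61, EGR1, EGR3, NR4A1 and NR4A2 rose (7 members); over all genes none did. fry gave an adjusted p of 0.377 for the list. camera called it with a preset correlation but not with an estimated one (adjusted p = 0.18 with an estimated correlation). The number of members called over the list alone was 0 without K1, 15 without K4, 4 without the participant term and 2 without S3 and K5, where 32 members were higher and 5 lower. FOS, a partner in the AP-1 transcription factor, was higher in 4 of 5 pairs (2.83 ± 1.1) and moved from 1520 to 734 CPM in K4.

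Interferon and antigen presentation genes lay lower in the ketogenic resections, mostly those of K3 and K4. The type I interferon score moved by -1.66 in K3, -1.42 in K4 and -0.70 in K5 but by 0.16 in K1 and -0.10 in K2, and the MHC class I score by -1.63 in K3, -1.21 in K4 and -0.06 to 0.03 in the others. Leaving out K3 took the mean of the MHC class I score from -0.58 to -0.32. Some immune cell scores were lower in these 2 resections as well, by -1.06 and -0.80 for T cells, -1.20 and -0.88 for macrophages and -0.75 and -2.15 for cytotoxic lymphocytes in K3 and K4. The mast cell and eosinophil score moved by -0.65 in K3 and 0.61 in K4, and the B cell and plasma cell score by -0.70 and 0.04. In the type I interferon list, which holds antiviral genes, 29 of 30 members were lower (median -0.64), among them HERC6 (-1.07 ± 0.25, lower in 5 of 5) and ISG15 (-1.26 ± 0.37, lower in 5 of 5). In the MHC class I list, 18 of 19 members were lower (median -0.60), with TAPBPL, a peptide editor, at -0.98 ± 0.30. Neither list passed: fry gave adjusted p = 0.775 and 0.797, and camera's calls with a preset correlation were lost (adjusted p = 0.537 and 0.696 with an estimated correlation). Without S3 and K5, 29 of 30 and 17 of 19 members were lower. In the checkpoint list, VTCN1 alone fell when adjusted over the list alone, and 0 members did without S3 and K5. IDO1, a tryptophan-degrading enzyme induced by interferon gamma, stood at 183 ± 58.8 CPM in the biopsies and 67.7 ± 80.0 CPM in the resections (-2.31 ± 0.74, lower in 4 of 5).

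Among the other lists in the ketogenic pairs, 35 of 37 proliferation genes were higher (median 0.60, fry adjusted p = 0.864; adjusted p = 0.795 with an estimated correlation). The score of that list moved by 1.59 in K4 and 1.81 in K5 but by -0.69 in K1 and -0.21 in K3, and 32 of 37 members were higher without S3 and K5 (median 0.23). TOP2A, a topoisomerase of dividing cells, stood at 1.05 ± 0.45 (0.60 ± 0.36 without K4). In 25 of 30 members the endometrial epithelium list was lower (median -0.28, fry adjusted p = 0.864; adjusted p = 0.795 with an estimated correlation). The mucin gene MUC1 stood at -1.11 ± 0.32 and the receptor gene ERBB3 at -0.65 ± 0.22, each lower in 5 of 5 pairs. Of 16 mast cell and eosinophil genes 13 were higher (median 1.07, fry adjusted p = 0.864; adjusted p = 0.817 with an estimated correlation). All 72 ribosomal protein genes were higher, by a median of 0.33 (fry adjusted p = 0.864; adjusted p = 0.817 with an estimated correlation), and 58 of 72 were without S3 and K5 (median 0.11). Of 40 non-polyadenylated RNAs 28 were higher, with a median of 0.56 (fry adjusted p = 0.864; adjusted p = 0.795 with an estimated correlation). Their score moved by 0.91 in K5 and by -0.04 to 0.11 in the other ketogenic pairs, and 18 of 34 were higher without S3 and K5 (median 0.19). Of the 38 lists, fry called 0 (2 at an unadjusted p under 0.05), camera called 15 with a preset correlation and 0 with an estimated one.

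**Figure D1:**
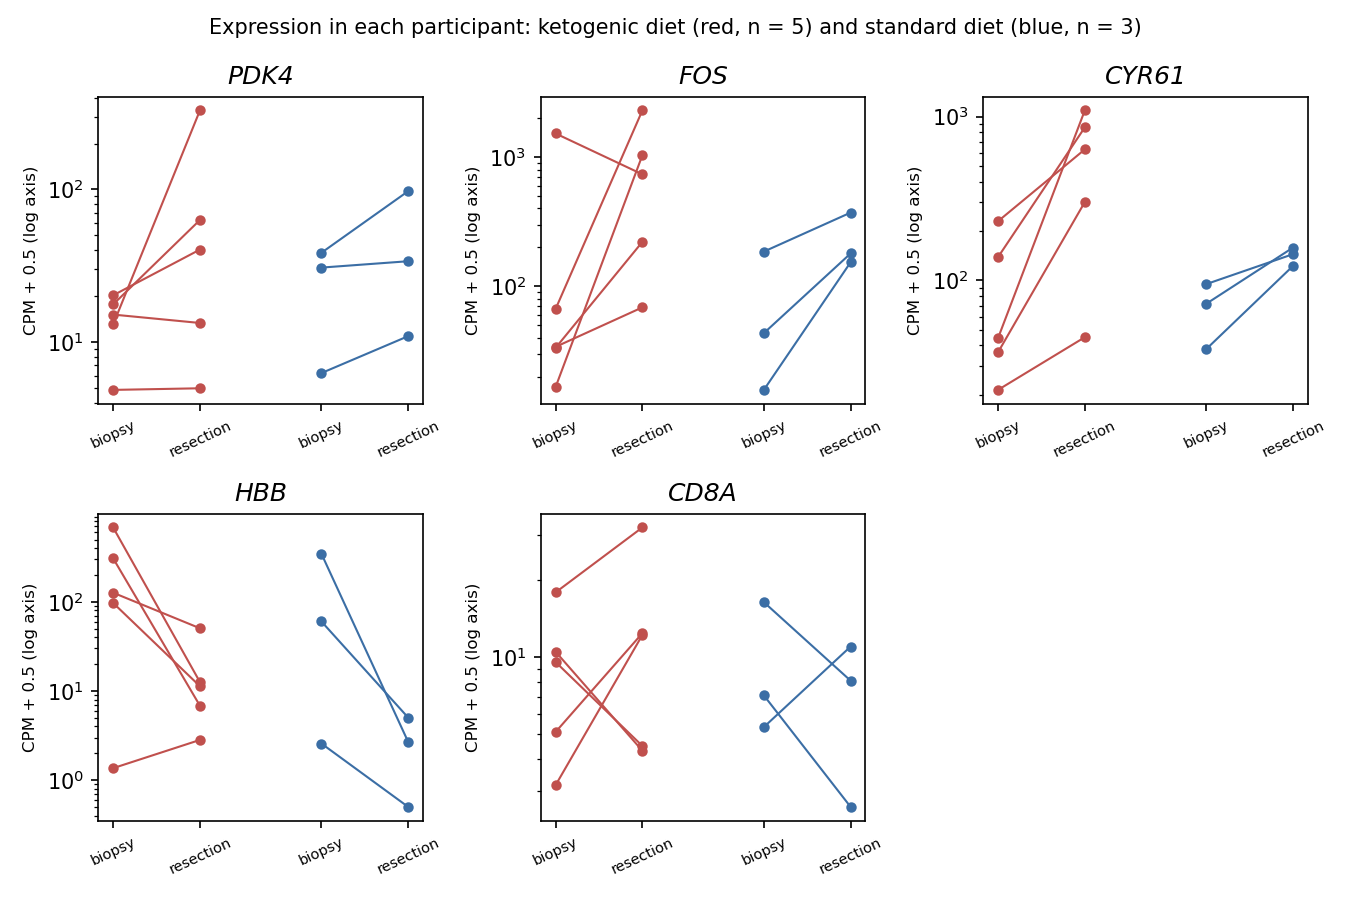
CPM + 0.5 on a log axis for 5 genes, with a line from biopsy to resection for each participant on the ketogenic diet (red, n = 5) and the standard diet (blue, n = 3). CYR61 is higher in the resection of 8 of 8 participants, FOS in 7 of 8 and HBB lower in 7 of 8, while CD8A goes both ways in each diet.

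On the standard diet, vessel and muscle genes were higher in the resections on average and red cell genes lower. The pairs differed in the first 2. The endothelium and pericyte score moved by -0.20 in S1, 0.90 in S2 and 1.22 in S3, and the smooth muscle score by 0.08, 1.01 and 3.93. MMRN2, a matrix protein of endothelial cells, stood at 13.5 ± 9.51 CPM in the biopsies and 31.3 ± 24.6 CPM in the resections (1.16 ± 0.24, higher in 3 of 3 pairs). DGKG, a diacylglycerol kinase (2.59 ± 0.52), LRRC2 (2.31 ± 0.51) and CTGF, a matrix protein and target of YAP (1.85 ± 0.43), were higher in 3 of 3 pairs as well. HSH2D, an adaptor protein of blood cells (-1.17 ± 0.26), MIR429 (-2.62 ± 0.60) and the haemoglobin genes HBA2 (-6.26 ± 1.59) and HBB (-5.58 ± 1.64) were lower in 3 of 3. HBA1 and HBA2 are near-identical, so the split of reads between them is uncertain. edgeR called 0 of 19302 genes (smallest adjusted p = 1; 447 at an unadjusted p under 0.05, 226 higher and 221 lower), and limma voom called 0. DESeq2 called 9 genes, among them MMRN2 (adjusted p = 0.000777), DGKG (0.00194), LRRC2 (0.00261), CTGF (0.0378), HSH2D (0.0297), MIR429 (0.00927), HBA2 (0.00201) and HBB (0.00218). edgeR without S3 and K5 called 0 genes (94 higher and 100 lower at an unadjusted p under 0.05), and values were 1.13 ± 0.27 for MMRN2, 2.99 ± 0.61 for DGKG and 1.56 ± 0.37 for CTGF.

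All 9 red blood cell genes were lower in the standard diet resections, by a median of -3.59, and HBA1, HBA2 and HBB fell when adjusted over the list alone. fry gave adjusted p = 0.751 (adjusted p = 0.318 with an estimated correlation). The count of 3 was 0 without S1, 0 without S2, 0 without S3 and K5, and 6 without the participant term. With S3 and K5 left out, 8 of 10 members were lower and the median was -0.82. All 28 endothelium and pericyte genes were higher (median 0.67, fry adjusted p = 0.751, camera adjusted p = 0.586 with an estimated correlation), and MMRN2 rose when adjusted over the list alone. Without S3 and K5, 21 of 28 were higher (median 0.41) and 0 rose over the list alone. All 26 smooth muscle genes were higher, by a median of 1.87 (fry adjusted p = 0.751; adjusted p = 0.534 with an estimated correlation), with FLNC, a filamin of muscle, at 2.19 ± 0.83 (1.23 ± 0.75 without S3). Without S3 and K5, 23 of 26 were higher and their median was 0.44. Over that list alone 0 members passed, and 14 did without S1. The collagen gene list was higher in 29 of 32 members (median 0.95, fry adjusted p = 0.751; adjusted p = 0.586 with an estimated correlation), and in 23 of 32 without S3 and K5 (median 0.42). The matrix proteoglycan gene LUM stood at 1.93 ± 0.69 (1.27 ± 0.73 without S3). Of 29 T cell genes 26 were lower (median -0.56, fry adjusted p = 0.805; adjusted p = 0.783 with an estimated correlation), with the homing receptor gene CCR7 at -1.79 ± 0.73. Of 37 immediate early genes 24 were higher (median 0.30), 0 passed over the list alone, and fry gave adjusted p = 0.751 (adjusted p = 0.586 with an estimated correlation). Of 72 ribosomal protein genes 69 were lower (median -0.29, fry adjusted p = 0.805; adjusted p = 0.793 with an estimated correlation), and 28 of 40 non-polyadenylated RNAs were higher (median 0.24, fry adjusted p = 0.805; adjusted p = 0.783 with an estimated correlation), against 28 of 34 without S3 and K5 (median 0.56). fry called 0 of 38 lists (1 at an unadjusted p under 0.05), and camera called 20 with a preset correlation and 0 with an estimated one.

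The difference between both diets' changes is the comparison that bears on the diet itself. KCNJ16, a potassium channel subunit, was higher in 5 of 5 ketogenic and lower in 3 of 3 standard diet resections, a difference of 2.14 ± 0.40. PPP5D1 went the same way (3.21 ± 0.80) at under 1 CPM, and CHI3L1, a secreted chitinase-like protein of macrophages and tumour cells, the opposite way (-2.13 ± 0.51, lower in 5 of 5 and higher in 3 of 3). IL7R, the interleukin 7 receptor of T cells, was higher in 5 of 5 and lower in 3 of 3 (2.49 ± 0.89), and CD36, a fatty acid transporter, was higher in 4 of 5 and lower in 3 of 3 (1.81 ± 0.57). edgeR called 0 of 19302 genes (smallest adjusted p = 1; 202 at an unadjusted p under 0.05, 104 higher and 98 lower), and limma voom called 0. DESeq2 called only KCNJ16 (adjusted p = 0.0374). edgeR without S3 and K5 called 0 genes (232 at an unadjusted p under 0.05), with KCNJ16 at 1.87 ± 0.42, PPP5D1 at 2.70 ± 0.82, CHI3L1 at -1.64 ± 0.50, IL7R at 3.21 ± 1.13 and CD36 at 2.35 ± 0.50.

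No insulin signalling gene passed a test of the difference. INSR, the insulin receptor, stood at -0.29 ± 0.37 in the ketogenic and 0.45 ± 0.47 in the standard diet pairs, a difference of -0.74 ± 0.60 (-0.24 ± 0.72 without S3 and K5); its ketogenic value was 0.09 without K4. IGF1R, the receptor of insulin-like growth factor 1, gave a difference of -0.03 ± 0.24 and the receptor substrate gene IRS1 0.21 ± 0.53 (-0.12 ± 0.42 without K1). The score of the 49 insulin and IGF receptor signalling genes moved by 0.04 ± 0.21 (SD, n = 5) on the ketogenic and 0.10 ± 0.12 (SD, n = 3) on the standard diet. The exact permutation p was 0.732 (adjusted p = 0.989), and 0.867 without S3 and K5. Without K4 the ketogenic mean was 0.12 and the difference 0.02 in place of -0.06. Without K1 that mean was -0.02 and the difference -0.13. FOXO target genes, which rise when insulin is low, moved by 0.02 ± 0.56 and 0.16 ± 0.19 (exact permutation p = 0.75, adjusted p = 0.989). Of the ketogenic pairs only K4 moved down (-0.90), and leaving it out took the ketogenic mean to 0.25 and the difference from -0.14 to 0.08. Leaving out K1 took the ketogenic mean to -0.14 and the difference to -0.30. In the ketogenic pairs their median was negative (-0.10), with 13 of 29 members higher, while their mean (0.04) and fry's direction were positive; 14 of 28 were higher without S3 and K5 (median -0.04).

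Of the 38 list scores, that of fatty acid oxidation gave the lowest permutation p of the difference. It moved by 0.10 ± 0.15 (SD, n = 5) on the ketogenic and -0.17 ± 0.18 (SD, n = 3) on the standard diet, a difference of 0.27 (exact permutation p = 0.0714, adjusted p = 0.989; difference 0.20 and p = 0.2 without S3 and K5, 0.17 without S3). Of its 42 members 32 had a positive difference (median 0.18, fry adjusted p = 0.994; adjusted p = 0.831 with an estimated correlation), with the mitochondrial isomerase gene ECI1 at 0.95 ± 0.41 (0.38 ± 0.31 without S3 and K5). CPT1A, which carries fatty acids into mitochondria, stood at 0.40 ± 0.22 and 0.28 ± 0.28, and PDK4, a kinase that holds back glucose oxidation, at 1.34 ± 0.64 and 0.78 ± 0.75 in the ketogenic and standard diet pairs. Without K4, where PDK4 went from 12.5 to 329 CPM, its ketogenic value was 0.68 ± 0.36 and the difference -0.10 ± 0.55 in place of 0.56 ± 0.98. The ketone body list had 7 of 17 members with a positive difference, a median of -0.03 against a mean of 0.25 (fry adjusted p = 0.994). Without S3 and K5, 6 of 17 were positive (median -0.07, fry adjusted p = 0.996), and 1 member rose over the list alone. In the ketogenic pairs of that setting, 2 ketone body members and 1 fatty acid oxidation member rose over their list alone. FASN, the fatty acid synthase, stood at -0.05 ± 0.23 and -0.28 ± 0.29 (-0.03 ± 0.35 on the standard diet without S3 and K5).

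No immune cell gene or score named here passed a test of the difference. CD8A, of cytotoxic T cells, stood at 0.37 ± 0.63 on the ketogenic diet (higher in 3 of 5 pairs) and -0.56 ± 0.80 on the standard diet (higher in 1 of 3), a difference of 0.94 ± 1.02 (0.33 ± 1.32 without S3 and K5). Its ketogenic value was -0.09 without K1. CD3E, of all T cells, gave a difference of 1.06 ± 1.02 (0.19 without S1), the protease gene GZMB 0.75 ± 1.31 (0.13 without K1) and CD68, of macrophages, 0.04 ± 0.68. The T cell list had a positive difference in 28 of 29 members (median 0.94; 28 of 29 and 0.61 without S3 and K5), but its score moved by 0.22 ± 1.15 (SD, n = 5) and -0.54 ± 1.04 (SD, n = 3), with exact permutation p = 0.393 (adjusted p = 0.989; p = 0.667 without S3 and K5); these means were -0.14 without K1 and -0.01 without S1. fry gave an adjusted p of 0.994, and camera's call with a preset correlation was lost (adjusted p = 0.95 with an estimated correlation). Scores of cytotoxic lymphocytes (-0.27 ± 1.19 and -0.39 ± 0.68; exact permutation p = 0.786), macrophages (-0.11 ± 1.06 and -0.16 ± 0.49; 0.893) and the type I interferon list (-0.74 ± 0.79 and -0.18 ± 0.11; 0.268) passed no test either. The ketogenic means were 0.20 without K4 for cytotoxic lymphocytes and 0.16 without K3 for macrophages, so that leaving out 1 participant turned each sign. Without K1 these ketogenic means were -0.51 and -0.49, and without S2 the standard diet means were -0.78 and -0.45.

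Structural lists also stayed below the threshold in the difference of the changes. The smooth muscle score moved by 0.30 ± 0.71 (SD, n = 5) and 1.67 ± 2.01 (SD, n = 3), with 3.93 in S3 alone (exact permutation p = 0.161; p = 0.6 without S3 and K5). Leaving out S3 took its standard diet mean to 0.54 and the difference from -1.37 to -0.25, and leaving out S1 took the difference to -2.17. Its ketogenic mean was 0.08 without K1, 0.48 without K4 and 0.14 without K5. The red blood cell score moved by -1.16 ± 1.11 and -2.16 ± 0.80 (exact permutation p = 0.232), the proliferation score by 0.55 ± 1.1 and 0.21 ± 0.14 (0.643), and the ribosomal protein score by 0.32 ± 0.82 and -0.29 ± 0.22 (0.25). The ketogenic means were 0.24 for proliferation and 0.12 for ribosomal proteins without K5, 0.29 and 0.13 without K4, and 0.87 and 0.60 without K1. For red blood cells the ketogenic mean was -0.75 without K4, and the difference went from 1.00 to 0.63 without S3. Of the 38 lists, fry called 0 (0 at an unadjusted p under 0.05), camera called 14 with a preset correlation and 0 with an estimated one, and the exact permutation test of the scores called 0 (0 at an unadjusted p under 0.05).

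**Figure D2:**
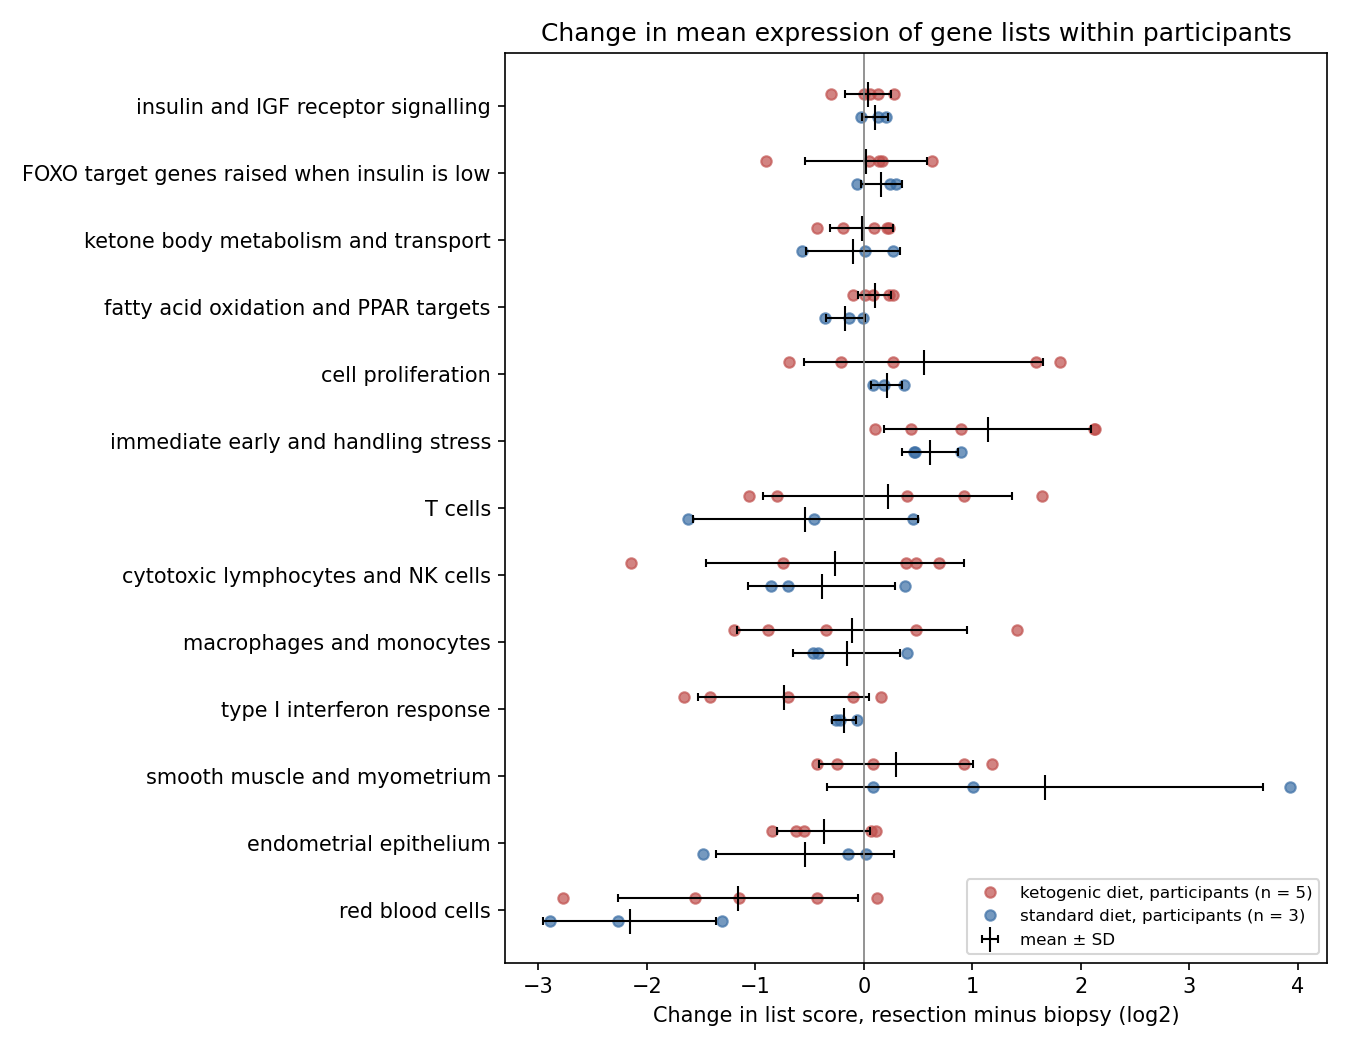
Change in list score (mean log2(CPM + 0.5) of the members, resection minus biopsy) for 13 gene lists, with a point per participant on the ketogenic (red, n = 5) and standard diet (blue, n = 3) and bars for the mean ± SD. The immediate early score is above 0 in 8 of 8 participants and the red blood cell score below 0 in 7 of 8, while insulin signalling stays near 0 (0.04 ± 0.21 and 0.10 ± 0.12).

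Across both diets, the mean change from biopsy to resection gave the smallest adjusted p of the comparisons (0.364, MIR200A at -3.14 ± 0.40). MIR200B (-3.19 ± 0.48) and MIR429 (-2.47 ± 0.38), of the same epithelial microRNA family, were lower in 8 of 8 pairs. CCDC88A (0.95 ± 0.16), MMRN2 (0.85 ± 0.15), EGR1 (2.19 ± 0.43) and THBS1, a matrix protein released by platelets and stroma (1.93 ± 0.43), were higher in 8 of 8. SLC16A7, a carrier of pyruvate and ketone bodies, was higher in 8 of 8 (1.17 ± 0.26), and VTCN1 (-1.18 ± 0.27) and MUC1 (-1.06 ± 0.26) were lower in 8 of 8. edgeR called 0 of 19302 genes (945 at an unadjusted p under 0.05, 421 higher and 524 lower), and limma voom called 0. DESeq2 called 76 (39 higher, 37 lower), among them MIR200A (adjusted p = 1.8e-09), MIR200B (9.22e-07), MIR429 (1.46e-08), CCDC88A (0.000131), MMRN2 (9.22e-07), EGR1 (7.53e-05), THBS1 (0.000723), SLC16A7 (0.000656), VTCN1 (0.0172) and MUC1 (0.0331). edgeR without S3 and K5 called 0 (463 at an unadjusted p under 0.05), with MIR200A at -3.02 ± 0.42, CCDC88A at 0.82 ± 0.18, EGR1 at 1.77 ± 0.48 and VTCN1 at -1.26 ± 0.32.

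The immediate early score was higher in the resection of 8 of 8 participants, by 0.94 ± 0.78 (SD, exact sign-flip p = 0.00781, adjusted p = 0.148). That p is the smallest that 8 pairs can give, and for a single list it cannot pass after adjustment over 38. Of the 37 members of the list, 14 rose when adjusted over the list alone. That count was 5 without K1, 7 without K5, 6 without S1, 4 without S2, 4 without S3, 2 without S3 and K5, 5 with the non-polyadenylated score as covariate and 2 without the participant term. fry gave an adjusted p of 0.293 (adjusted p = 0.213 with an estimated correlation). The red blood cell score was lower in 7 of 8 participants (-1.53 ± 1.07; exact sign-flip p = 0.0156, adjusted p = 0.148), and ALAS2, HBA1, HBA2 and HBB fell over the list alone. Those 4 became 0 without S2 and 1 with that covariate, and the median of the list went from -2.66 to -0.66 without S3 and K5; fry gave an adjusted p of 0.244 (adjusted p = 0.213 with an estimated correlation). The fatty acid synthesis score was lower in 7 of 8 (-0.10 ± 0.09; exact sign-flip p = 0.0156, adjusted p = 0.148), and 17 of its 25 members were lower (fry adjusted p = 0.471). All 19 MHC class I genes were lower (median -0.49, fry adjusted p = 0.484). All 26 smooth muscle genes were higher (median 1.21, fry adjusted p = 0.471), and 29 of 30 endometrial epithelium genes were lower (median -0.38, fry adjusted p = 0.471). For each of these lists camera gave adjusted p = 0.53 with an estimated correlation. With S3 and K5 left out, 21 of 26 smooth muscle genes were higher (median 0.51), and 23 of 30 epithelium genes (median -0.14), 17 of 19 MHC class I genes (median -0.50) and 15 of 25 fatty acid synthesis genes were lower. Of insulin signalling genes 32 of 49 were higher (fry adjusted p = 0.5). The non-polyadenylated RNA score was higher in 7 of 8 participants (0.21 ± 0.31, exact sign-flip p = 0.0156, adjusted p = 0.148). Without S3 and K5 that score was higher in 5 of 6. SLC16A7, MMRN2 and THBS1 rose and VTCN1 fell over the ketone body, endothelium, wound and checkpoint lists alone. Without S3 and K5, 2 members of the ketone body list rose, and 0 members passed over the endothelium, wound and checkpoint lists alone. fry called 0 of 38 lists (3 at an unadjusted p under 0.05), and camera called 19 with a preset correlation and 0 with an estimated one. Across genes, which are not independent replicates, the changes on both diets, from different participants, correlated at r = 0.28 (Spearman 0.33), and 63.5% had the same sign.

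The biopsies precede the diet and compare the groups before it; 1 of the 3 standard diet biopsies, that of S3, has the library make-up described above. MEIS1, a homeobox gene, stood at 316 ± 59.5 CPM in the 5 biopsies of the ketogenic group and 48.3 ± 24.5 CPM in the 3 of the standard group (2.69 ± 0.43), and NDP, a ligand of Wnt receptors, at 28.4 ± 14.6 and 1.21 ± 0.308 CPM (4.54 ± 0.83). MAN1A1, a Golgi mannosidase (1.80 ± 0.37), and the cilium gene TEKT1 (5.71 ± 1.26) were higher too. PRPH, an intermediate filament gene, was lower (-4.60 ± 0.76; 0.215 ± 0.128 and 5.27 ± 2.88 CPM), and so was COLGALT2, a collagen galactosyltransferase (-3.34 ± 0.69). edgeR called 0 of 17956 genes (smallest adjusted p = 0.942; 899 at an unadjusted p under 0.05, 378 higher and 521 lower), and limma voom called 0. DESeq2 called 107 (79 higher, 28 lower), among them MEIS1 (adjusted p = 1.22e-06), NDP (1.22e-06), MAN1A1 (0.00226), TEKT1 (2.21e-05), PRPH (1.22e-06) and COLGALT2 (0.00145). edgeR without S3 and K5 called 0 (717 at an unadjusted p under 0.05), with MEIS1 at 2.77 ± 0.57, NDP at 4.74 ± 1.13 and PRPH at -5.09 ± 0.88.

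In the resections, ASRGL1, an asparaginase, stood at 502 ± 140 CPM in the ketogenic and 109 ± 47.0 CPM in the standard group (2.21 ± 0.44). IL32, a cytokine (2.25 ± 0.52), and the cilium assembly gene ZMYND10 (3.54 ± 0.85) were higher. KIF5C, a kinesin (-3.42 ± 0.54; 3.86 ± 2.12 and 41.6 ± 21 CPM), LOX, a collagen cross-linking enzyme (-2.34 ± 0.42; 15.9 ± 5.20 and 80.5 ± 41.9 CPM), and ARNT2, a transcription factor (-1.38 ± 0.27), were lower. edgeR called 0 of 18291 genes (smallest adjusted p = 0.889; 1009 at an unadjusted p under 0.05, 390 higher and 619 lower), and limma voom called 0. DESeq2 called 134 (85 higher, 49 lower), among them ASRGL1 (adjusted p = 0.000572), IL32 (0.00963), ZMYND10 (0.00233), KIF5C (2.55e-05), LOX (0.0014) and ARNT2 (0.00105). Of the genes DESeq2 called, 35 were shared by the biopsies and the resections. edgeR without S3 and K5 called 0 (718 at an unadjusted p under 0.05), with KIF5C at -2.91 ± 0.64, LOX at -2.46 ± 0.49, ASRGL1 at 2.16 ± 0.54 and ZMYND10 at 2.64 ± 0.83.

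Genes of ciliated epithelium, whose cells line parts of the endometrium, were higher in the ketogenic group before and after the diet. In the biopsies 24 of 26 were higher (median 2.46), and 14 rose when adjusted over the list alone; in the resections 24 of 26 were higher (median 2.78), and 13 rose. The scores were 3.65 ± 1.19 (SD, n = 5) and 1.90 ± 0.23 (SD, n = 3) in the biopsies (exact permutation p = 0.0536, adjusted p = 1) and 3.85 ± 1.53 and 1.92 ± 0.49 in the resections (exact permutation p = 0.0893, adjusted p = 0.792). fry gave adjusted p = 0.984 and 0.885 (adjusted p = 0.945 and 0.603 with an estimated correlation). The 14 in the biopsies became 2 without K1, 2 without K5, 0 without S1, 0 without S2, 1 without S3 and 1 without S3 and K5, where 22 of 26 were higher (median 1.95). The 13 in the resections became 8 without K1, 8 without K4, 5 without K5, 5 without S2, 0 without S3 and 0 without S3 and K5, where 22 of 26 were higher (median 1.91).

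The non-polyadenylated list was lower in the ketogenic group in 22 of 23 members in the biopsies (12 fell over the list alone) and 28 of 29 in the resections (14 fell). S3 had the highest scores, and without S3 and K5 0 fell in both, with 17 of 23 and 21 of 24 lower. Smooth muscle genes were lower in 22 of 26 members in the resections, where 4 fell over the list alone, ACTG2, DES and PGM5 among them (fry adjusted p = 0.885; adjusted p = 0.603 with an estimated correlation) and 0 did without S3 and K5, where 14 of 26 were lower. Insulin signalling genes were higher in 22 of 47 members in the biopsies (fry adjusted p = 0.984) and 22 of 48 in the resections (0.99), with medians of -0.05 and -0.15. That direction turned without S3 and K5, to 30 of 47 higher in the biopsies (median 0.17) and 28 of 48 in the resections (median 0.11). T cell genes were higher in 11 of 29 (0.984) and in 25 of 29 (0.99; adjusted p = 0.991 with an estimated correlation). Fatty acid oxidation genes were higher in 32 of 41 in the resections (median 0.50, fry adjusted p = 0.885; adjusted p = 0.603 with an estimated correlation), with the reductase gene DECR1 at 1.05 ± 0.36. Ribosomal protein genes were higher in 68 of 72 in the biopsies and 71 of 72 in the resections (fry adjusted p = 0.984 and 0.885; adjusted p = 0.945 and 0.648 with an estimated correlation). Their scores were 7.59 and 7.25 in S3 and 8.63 to 10.15 elsewhere, and without S3 and K5 the counts were 45 of 72 and 66 of 72, with medians of 0.07 and 0.39 in place of 0.32 and 0.90. fry called 0 of 38 lists in the biopsies (0 at an unadjusted p under 0.05) and 0 in the resections (1 at an unadjusted p under 0.05); camera called 10 and 11 with a preset correlation and 0 with an estimated one.

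**Figure D3:**
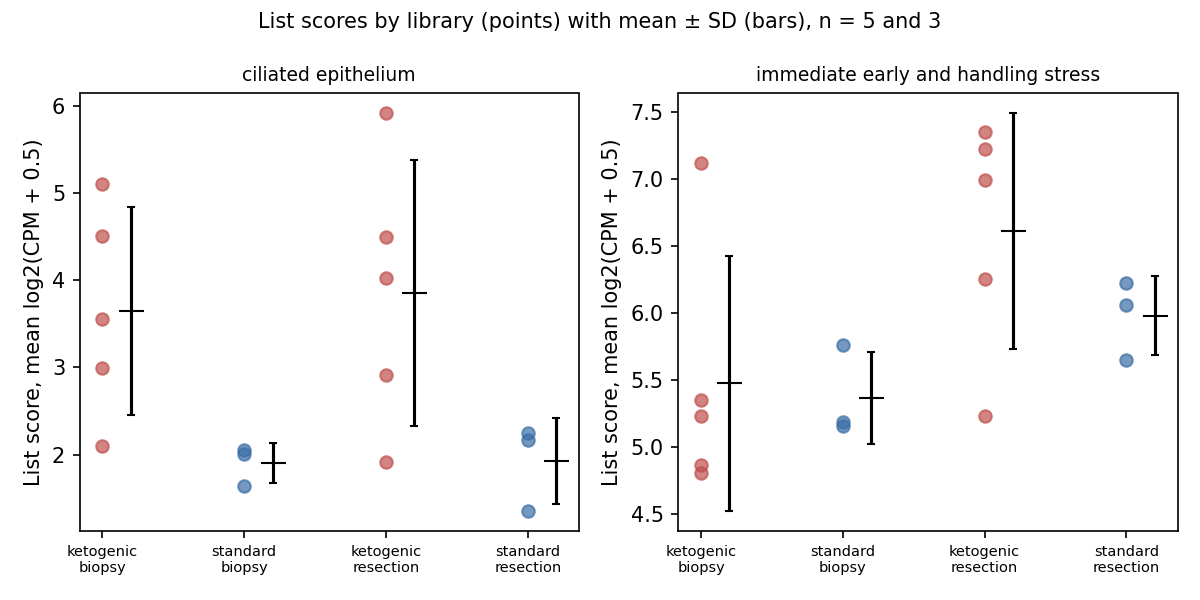
List scores (mean log2(CPM + 0.5) of the members) of ciliated epithelium and of immediate early genes, with a point per library and bars for the mean ± SD, in biopsies and resections of the ketogenic (red, n = 5) and standard diet groups (blue, n = 3). The ciliated score of the ketogenic group runs from 2.10 to 5.10 in the biopsies, above the 3 standard diet biopsies (1.64 to 2.06), and the resections overlap.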

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

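The set of genes tested for opposite directions was widened to all genes named in the difference of the changes after the results were seen. The other tests in this part were not chosen on their results.

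The 178 groups tested held the 5 ketogenic biopsies, resections or changes, or the changes of all 8 participants. Of these groups, 16 had a sample far from the others, where chance marks about 1 in 20 groups. The standard diet libraries were not tested as a group, so single libraries could be marked in the ketogenic group only. Several marks fell on the same few libraries. The biopsy of K2 was high in the type I interferon list (score 7.09, nearest other ketogenic biopsy 5.29), the MHC class II list (7.57 against 6.06) and the MHC class I list (8.52 against 7.38), and low in the ketone body list (2.93 against 3.38). The biopsy of K4 was high in immediate early genes (7.12 against 5.35) and in cytotoxic lymphocyte genes (3.04 against 1.65). The biopsy of K1 was high in nuclear-encoded oxidative phosphorylation genes (7.03 against 6.33) and ribosomal protein genes (10.2 against 9.11).

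Among the ketogenic resections, MALAT1 reached 23800 CPM in K5 (nearest other 1540), and the adipocyte list was low in K3 (score 1.1, nearest other 2.09). In the changes from biopsy to resection, K4 stood apart in the FOXO target list over all 8 participants (-0.9, nearest other -0.06). K4 also stood apart in the secretory and decidual endometrium list, at -2.74, both within the ketogenic group (nearest other -0.14) and over all 8 (-0.82). The smooth muscle list stood apart in S3 (3.93, nearest other 1.18). The non-polyadenylated list stood apart in K5, at 0.91, both within the ketogenic group (nearest other 0.11) and over all 8 (0.37).

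The 174 genes named in the difference of the changes and the 38 lists were checked. Of these, 4 genes and 0 lists moved one way in all 5 ketogenic pairs and the opposite way in all 3 standard diet pairs. Chance gives 0.78%. The rule for named genes favours small p values in that same difference, which makes such patterns more frequent. The differences between both changes were 2.14 for KCNJ16, 3.21 for PPP5D1, -2.13 for CHI3L1 and 2.49 for IL7R. Each difference was tested within the paired model, and edgeR gave an adjusted p = 1 for all 4; DESeq2 gave KCNJ16 an adjusted p = 0.0374.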

How the results depend on the processing

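Leaving out S3 and K5 together, and the list tests with each participant left out, were chosen after seeing the data; the other tests were planned. edgeR called 0 genes in each of the 6 comparisons and under each of its alternatives, and limma voom called 0. DESeq2 called 33 genes in the change on the ketogenic diet, 9 on the standard diet, 1 in the difference, 76 in the mean change, 107 in the biopsies and 134 in the resections; the cause was not tested. At an unadjusted p under 0.05 edgeR gave 655, 447, 202, 945, 899 and 1009 genes in that order, limma voom 1260, 700, 474, 1200, 647 and 522, and DESeq2 1111, 825, 378, 1593, 1250 and 1314. fry called 0 of 38 lists in each comparison in the main fit, with the non-polyadenylated score as covariate and without S3 and K5. The same held with each participant left out and, within participants, without the participant block. Its calls were not counted under the other alternatives. camera with a preset correlation called 15, 20, 14, 19, 10 and 11 lists, and 0 with an estimated correlation; the cause was not tested further. The permutation test of list scores called 0 lists under each alternative, which says nothing about stability: its smallest p of 0.0179 (0.0667 without S3 and K5) for a single list cannot pass after adjustment over 38. With each participant left out in turn, the counts of called genes and lists ranged from 0 to 0.

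The fit without the participant block called 0 genes and 0 lists, and so changed no call over all genes or lists. At an unadjusted p under 0.05 it gave 259, 153, 64 and 300 genes in the 4 comparisons within participants. Single participants moved such edgeR counts by over 1.5 times. Without S3 the change on the standard diet gave 138 and the mean change 356, and without S2 the change on the standard diet gave 945, the difference 402 and the resections 1785. Without S1 the difference gave 309. Among named genes the sign turned in 97 of 3320 values on the ketogenic diet, 82 of 3258 on the standard diet and 143 of 2917 in the difference. It turned in 103 of 2994 in the mean change, 82 of 2393 in the biopsies and 79 of 2343 in the resections. Counted by gene, it turned in some setting for 45 of 188, 37 of 185, 54 of 174, 40 of 179, 45 of 154 and 43 of 151, in that order. Called values reversed 0 times, but only 17, 9, 1, 32, 15 and 19 of these genes were called in any alternative. Depth limits the microRNA features and PPP5D1, which held few counts.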

Other observations

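The list counts without S3 and K5, the tests of explanations in the 3 patterns, the limit of 500 for microRNA numbers and the measure used for the splits were chosen after the results were seen; the tests of gene lists were planned.

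Several lists stayed below the threshold while most of their members lay on one side. Dendritic cell genes were lower in 17 of 18 members on the standard diet (median -0.81, fry adjusted p = 0.751; adjusted p = 0.586 with an estimated correlation). Their difference of changes was positive in 15 of 18 (fry adjusted p = 0.994; adjusted p = 0.831 with an estimated correlation). In that difference FLT3, a receptor of dendritic cell precursors, stood at 2.41 ± 1.08 and CD83, a marker of mature dendritic cells, at 1.07 ± 0.47, both with an edgeR adjusted p = 1. Neutrophil genes were lower in 17 of 18 members in the mean change (median -0.65, fry adjusted p = 0.518; adjusted p = 0.53 with an estimated correlation), and in 12 of 18 without S3 and K5 (median -0.24); their score went from 3.44 to 1.32 in S3. Nuclear-encoded oxidative phosphorylation genes were higher in the ketogenic than in the standard diet resections in 47 of 54 members (median 0.48, fry adjusted p = 0.906; adjusted p = 0.991 with an estimated correlation). The resection of S3 had a score of 5.02, against 6.23 to 6.68 in the others, and 33 of 54 were higher without S3 and K5 (median 0.10). CPA3, a mast cell protease, stood at 0.469 ± 0.473 CPM (SD, n = 5) in the ketogenic biopsies and 4.02 ± 4.69 CPM in the resections, a change of 3.11 ± 1.24 that was positive in 4 of 5 pairs (edgeR adjusted p = 1).

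Immediate early genes were higher in the resections. The score was higher in all 6 participants other than S3 and K5 (mean 0.82). A different preparation of S3 and K5 does not give the rise in these 6. The pattern was picked with 8 of 8 participants higher. The exact sign-flip p of 0.0312 over these 6 was therefore fixed beforehand and adds no support. The 3 standard diet pairs moved by 0.61 ± 0.26 (SD). That they rose was likewise fixed by picking a pattern with 8 of 8 higher, so it does not tell against the diet. Sign flips over 3 pairs cannot give a p under 0.25, so they decide nothing about the diet. How the tissue was taken remains open: the score was higher in 8 of 8 participants, and every pair sets a biopsy against an operation. The way of taking the tissue cannot be told apart from the weeks between the samples, and either may contribute.

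The mean of the microRNA features with numbers under 500 was lower in the resections of 8 of 8 participants (34 features, -0.56 ± 0.22 SD, exact sign-flip p = 0.00781). The 120 features numbered 500 and above averaged 0.01 ± 0.06. Most of the 34 held under 1 CPM on average, near the pseudocount of 0.5. Not all fell: MIR7-1, at 3.58 CPM, was higher in 8 of 8 (0.53 ± 0.32), and MIR145 averaged 0.48 ± 0.83. The mean was lower in all 6 participants other than S3 and K5 (-0.51 over these 6). A different preparation of S3 and K5 does not give the fall in these 6. The class was picked with 8 of 8 participants lower. The exact sign-flip p of 0.0312 over these 6 was therefore fixed beforehand and adds no support. A lower share of epithelial cells stays open, since the features minus the epithelium score gave -0.13 ± 0.43 (SD, n = 8); for MIR200A, MIR200B, MIR429 and MIR141 that value was -1.06 ± 0.26, but these include the 3 largest falls and hold few reads, which decides nothing. The change of 7 microRNAs minus their host genes was -0.69 ± 0.37, but most held under 1 CPM, so transcription of the host genes cannot be told apart either. A different recovery of short RNAs between biopsies and resections may also play a part and was not tested.

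Ciliated epithelium genes were higher in the ketogenic group. The diet is argued against as the source, since the difference was there in the biopsies and the difference of the changes was 0.18 ± 0.65 (SE), against a difference of 1.93 in the resections. The preparation of S3, the 1 biopsy with raised non-polyadenylated RNAs, is argued against as the whole source in the biopsies, since without S3 the difference was 1.80 ± 0.57 (SE; 95% margin 1.49) against 1.75 with all (1.44 ± 0.55 without S3 and K5). In the resections a different preparation of S3 and K5, which no label gives, stays open. The difference without them was 1.12 ± 0.58 (SE, 95% margin 1.83) from 4 against 2 participants. Chance differences between participants may account for the pattern, with an exact permutation p of 0.0536 in the biopsies, and differences between the tumours themselves were not tested.

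Other splits of the samples were compared by the number of genes at an unadjusted p under 0.05, since edgeR called 0. The change on the ketogenic diet (655 genes, highest other 1100; 13 of 16 splits as large) and on the standard diet (447, highest other 643; 3 of 4) have too few splits for a share under 0.05. Chance cannot be excluded for the difference of the changes (202, highest other 1784; 56 of 56 splits as large), the mean change (945, highest other 1810; 13 of 100 drawn of 128), the biopsies (899, highest other 3493; 30 of 56) or the resections (1009, highest other 2698; 28 of 56). Splits with several times the real count, as in the difference and the biopsies, may point to a structure of the samples other than the diet, which was not tested; genes that vary together could also give such counts by chance. In those other splits edgeR called at most 1 gene in the difference, 1 in the biopsies and 2 in the resections.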
